A study of Drosophila melanogaster with 2 samples.

How the data were processed

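Gene expression was measured in Drosophila melanogaster S2 cells on 2 Affymetrix Drosophila Genome 2.0 arrays, which carry short probes grouped into probe sets near the 3′ ends of transcripts. S2 is an established cell line derived from fly embryos with properties of macrophage-like blood cells. Both arrays belong to 1 group: cells soaked for 8 days, in 2 rounds of 4 days each, with dsRNA (double-stranded RNA) against GFP (green fluorescent protein). The fly genome holds no GFP gene, and no probe set identified as GFP was analysed here. The labels describe the treatment as done in duplicate and do not say whether the duplicates were grown apart or on different days, so the spread between them may be technical. No untreated cells or cells given another dsRNA were analysed here, so the effect of the dsRNA cannot be measured.

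Per the labels' protocols, total RNA was reverse transcribed from its poly(A) tails and amplified into biotin-labelled RNA, and 10 µg of it was hybridised for 16 hours. The design text gives 1 µg of starting RNA and the labelling protocol gives 2 µg. That text also names an Affymetrix Scanner 3000 and GeneChip Operating Software 1.2. The algorithm that turned probes into a probe set value, any array-wide scaling and any filter are not given in the sources used here. The authors deposited 1 linear signal intensity per probe set and array, with no detection call. The deposited intensities ran from 0.128 to 24533, with medians of 70.8 and 73.8 on replicates 1 and 2, and were used without further normalization. They are not counts, so precision is limited by the number of arrays.

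The platform annotation given for this work named 13647 of the 18952 probe sets by 1 gene. Another 402 had several genes and named none. The remaining 4903, of which 183 were control probe sets, had no row in the annotation. Symbols were brought up to date through gene identifiers in a RefSeq gene table of the release 6 fly assembly, which held 11894 of the 11983 genes with a probe set of their own. The other 89 kept the annotation's symbol. Of the 317 entries in the gene lists, 230 were measured by such a probe set, 86 had none, and 1 named a gene already in its list. 11 entries, such as CG4068, were matched through an older symbol or another letter case. Genes with no probe set of their own, AGO2, AGO1 and Dcr-1 among them, were not analysed here.

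A background limit was set on each array as the 95th percentile of the signals of 125 probe sets for 112 odorant and gustatory receptor genes, which a blood-like cell line is not expected to express. A gene was called detected where any of its probe sets lay above the limit on both arrays. By construction about 5% of receptor probe sets exceed the limit on each array. A level is the mean ± SD of the 2 arrays for the gene's probe set with the highest mean. Probe sets differ in their response, so levels of different genes were not set against each other. For log2 differences, signals under 1 were raised to 1.

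The design has no second group. Each of 22 gene lists was therefore compared with all other genes of the arrays by a two-sided Fisher's exact test of detected against not detected, leaving out the receptor genes, with Benjamini-Hochberg adjustment over the lists. Genes are not independent replicates, and the correlation between genes cannot be estimated from 2 arrays, so these p-values describe the lists on these arrays. The lists, the 95th percentile limit, the list tests, most other settings tried and the rule for named genes were fixed before the data were examined. The tests of neighbours and the settings named as such in the closing part were chosen later. That rule took the first 4 measured members of each list in its written order, up to 2 further members whose detection went against the list's majority, all members of the siRNA list and of the list of siRNA loci, and the 10 detected genes with the largest difference between the arrays. Genes named outside that rule were chosen after their values were seen.

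Tests of convergent and divergent gene pairs had been planned but could not be run, because the gene table used here gives no strand. In their place, neighbouring protein-coding genes were used whatever their strand. Overlapping neighbours were those whose annotated spans overlap by at least 1 bp with neither inside the other. Separate neighbours were adjacent genes with a gap of up to 5000 bp. Joint detection was tested with 100000 random re-pairings of left and right members, and the 2 kinds of neighbour with a two-sided Fisher's exact test. Odds ratios of joint detection were also pooled within classes of overlap or gap by the Mantel-Haenszel method, with normal-approximation intervals. This replacement and the pooled odds ratios were chosen after the gene table or the results were seen.

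The difference of a list between the arrays was placed among 10000 random lists of the same size, drawn from genes within 50 ranks of each member's signal. Draws past either end of the ranking were set to the last gene at that end. For lists with members near an end, that single gene was therefore drawn more often than others. Members of the list itself could be drawn, so a percentile is pulled towards the middle where members share the same ranks. The percentiles were not adjusted for the number of lists or families. Alternatives covered the limit, the rule for multiple probe sets, single arrays, quantile normalization, median scaling, the pseudocount, the overlap and the gap. In simulated data with the arrays' own mean signals and normal noise, 100% of probe sets changed 2.83-fold or 8-fold were called over 2-fold and 0 of the unchanged ones were. That noise had the same SD of the log2 difference, 0.227, for every probe set, whereas the real spread was wider among dim ones. The simulation therefore gives no rate of false calls for the real arrays. Random lists of 10 genes passed an unadjusted p of 0.05 in 1.2% of 500 draws, and lists drawn at 95% detected passed in 91.0%. Independent simulated pairs passed in 4.5% of 200 sets. For a true pooled odds ratio of 3 the median recovered was 2.99, and 96% of intervals held the true value. No gene was shared between simulated pairs, whereas the 6275 real separate pairs held only 8762 genes. These rates therefore do not carry over to the real pairs, whose p-values and intervals may be too narrow. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.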

Results

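The series holds 2 arrays of S2 cells treated with dsRNA against GFP, replicates 1 and 2 of a single group. The background limit was a signal of 146 on replicate 1 (95% bootstrap interval 104 to 175) and 136 on replicate 2 (109 to 180). On both arrays together 7262 of 18952 probe sets (38.3%) were above it, and 5886 of 11983 genes (49.1%) were detected. Of the 112 receptor genes that set the limit, 5 (4.46%) passed it on both arrays. The array holds 50 control probe sets named by a protein accession, and these reached at most 85.0 on replicate 1 and 70.3 on replicate 2, below the limit. The 3′ to 5′ signal ratio was 1.06 and 1.09 for actin, 2.46 and 2.29 for GAPDH, and 2.04 and 2.01 for eIF-4a on replicates 1 and 2. With a lower limit, drawn after seeing the data from those 50 control probe sets, 6972 genes were detected. All levels below are signals given as mean ± SD with n = 2. There was no second condition, so the comparisons are between gene groups on the same arrays, between neighbouring genes, and between the duplicate arrays.

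The series title concerns how endogenous siRNAs arise from bidirectional transcription, and the first question was which small RNA pathway genes were expressed in these cells. All 11 measured genes of the siRNA list were detected. Dcr-2, the Dicer that makes siRNAs, had a signal of 2128 ± 169, and r2d2, its dsRNA-binding partner, 994 ± 112. Hen1, the methyltransferase that modifies siRNA and piRNA 3′ ends, stood at 374 ± 21.1. The nuclease subunits trsn and Trax, which assist siRNA loading, had signals of 2192 ± 200 and 1068 ± 22.1, although 1 of the 2 Trax probe sets was below the limit. The helicase genes armi and Rm62 were at 1354 ± 113 and 8412 ± 317. Signals of the RISC-associated genes were 3071 ± 35.6 for Fmr1, 1936 ± 67.3 for vig and 5723 ± 162 for Tudor-SN, and Ars2 had 1339 ± 148. The share of 100% compared with 49.5% of other genes (Fisher's exact test, adjusted p = 0.00269).

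All 9 measured microRNA pathway genes were also detected (Fisher's exact test, adjusted p = 0.00563). The nuclear processing genes drosha and pasha had signals of 423 ± 16.5 and 321 ± 8.16. The dsRNA-binding protein gene loqs had 472 ± 61.7, and the exportin gene Ranbp21 had 1600 ± 52.9.

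Of 15 measured genes of the piRNA and germline list, 12 were detected, or 80.0% against 49.5% of other genes (Fisher's exact test, adjusted p = 0.0316). The PIWI-family genes aub and AGO3 had signals of 2968 ± 24.7 and 487 ± 37.9. The third PIWI-family gene, piwi, was not detected on both arrays, at 140 ± 5.54, but passed the limit on replicate 2 alone and the 90th percentile limit on both. The germline gene nanos, at 11.5 ± 9.15, and the piRNA gene qin, at 73.2 ± 10.7, were not detected either. Detected members outside the naming rule included bam (4293 ± 417), tud (2307 ± 50.8) and osk (223 ± 3.9, by 1 of 3 probe sets). The call for this list was lost when every probe set of a gene had to pass (73.3%), with replicate 1 alone (80.0%) and with the limit from 50 control probe sets (86.7%). Over all alternatives its adjusted p ran from 0.00871 to 0.112 (Fisher's exact test).

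The second question was whether genes that earlier work tied to endogenous siRNAs were expressed, and all 5 that were measured were detected. The loci thickveins (tkv), a BMP receptor gene, and klarsicht (klar), a gene for nuclear positioning, had signals of 620 ± 60.8 and 2053 ± 237. One of the 2 tkv probe sets was below the limit. CG7739 had 1633 ± 193. The DNA polymerase theta gene PolQ, also known as mus308, had 284 ± 27.7. The gene now listed as CG44774, for which CG4068 is an older name, had 3405 ± 360. Whether its probe set measures that transcript or a hairpin locus near it is not settled by the tables used here, so its place among the 5 is uncertain. The list passed the test (Fisher's exact test, adjusted p = 0.0437), but its genes were known partly from work in S2 cells, so the share is not independent evidence. The call was lost with either array alone, and over all alternatives the adjusted p ran from 0.0265 to 0.251 (Fisher's exact test).

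Markers of macrophage-like blood cells (hemocytes) were detected more often than other genes, in 16 of 18 measured cases or 88.9% (Fisher's exact test, adjusted p = 0.00288). Hml (hemolectin) had a signal of 4509 ± 520, Pxn (peroxidasin) 8028 ± 492 and the phagocytic receptor gene eater 231 ± 3.08. A second Pxn probe set was below the limit. NimC1, another phagocytic receptor gene, was not detected at 112 ± 21.7, nor was gcm, a transcription factor gene of early blood cells and glia, at 8.98 ± 0.729. Among markers of the other blood cell types, crystal cells and lamellocytes, 3 of 10 were detected, a share of 30% that was lower than the 49.6% of other genes without passing the test (Fisher's exact test, adjusted p = 0.36). The prophenoloxidase genes PPO1 and PPO2 were below the limit at 12.1 ± 0.0075 and 91.5 ± 46.4, as was lz at 48.7 ± 26.2. The 3 detected members were PPO3 (802 ± 99.9), the filamin gene cher (4198 ± 297) and the kinase gene msn (3330 ± 659).

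Markers of the testis and male accessory gland (0 of 12) and of the ovarian follicle and chorion (0 of 9) were not detected on both arrays. The sperm tail gene dj, for example, was at 9.59 ± 7.18, and the follicle cell gene tj at 21.5 ± 19.8. The adjusted p-values were 0.00269 and 0.00955 (Fisher's exact test). The chorion gene Cp15, at 137 ± 33.1, was above the limit on replicate 2 alone. With the limit from 50 control probe sets, 25% of the testis and 22.2% of the follicle genes were above it, and both calls were lost. Of 14 neuronal and glial markers 2 were detected (Fisher's exact test, adjusted p = 0.0219). The synaptic genes nSyb and brp were at 17.5 ± 8.62 and 73.4 ± 6.01, and the sodium channel gene para was at 28.7 ± 0.85. The detected pair was elav, an RNA-binding protein gene used as a neuronal marker, at 196 ± 18.2, and moody, a receptor gene of the glial blood-brain barrier, at 2172 ± 447. That list's call was lost with the limit from 50 control probe sets (28.6%) and among genes with a single probe set (20%). Of 11 muscle markers only Mf (myofilin) was detected, at 1562 ± 209 (Fisher's exact test, adjusted p = 0.0215 for the list). The troponin gene up was at 5.4 ± 0.83, the myosin light chain gene Mlc2 at 21.1 ± 0.535, and the actin genes Act88F and Act87E at 80.4 ± 34.8 and 31.4 ± 33.4.

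For 3 further tissue lists the share was lower than in other genes without passing the test. Of 8 fat body and yolk genes, Lsp2 (188 ± 45.0) and Npc2g (185 ± 14.1) were detected, while the yolk protein gene Yp1 was at 27.7 ± 23.7 (Fisher's exact test, adjusted p = 0.335). Of 6 photoreceptor genes 1 was detected, the eye transcription factor gene ey, at 215 ± 11.2 (adjusted p = 0.267, Fisher's exact test). Of 8 cuticle and epidermis genes 1 was detected, the polarity gene crb, at 499 ± 52.5 (adjusted p = 0.0967, Fisher's exact test). Under the stricter 99th percentile limit elav, ey, Lsp2, Npc2g and eater were no longer detected.

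**Figure D1:**
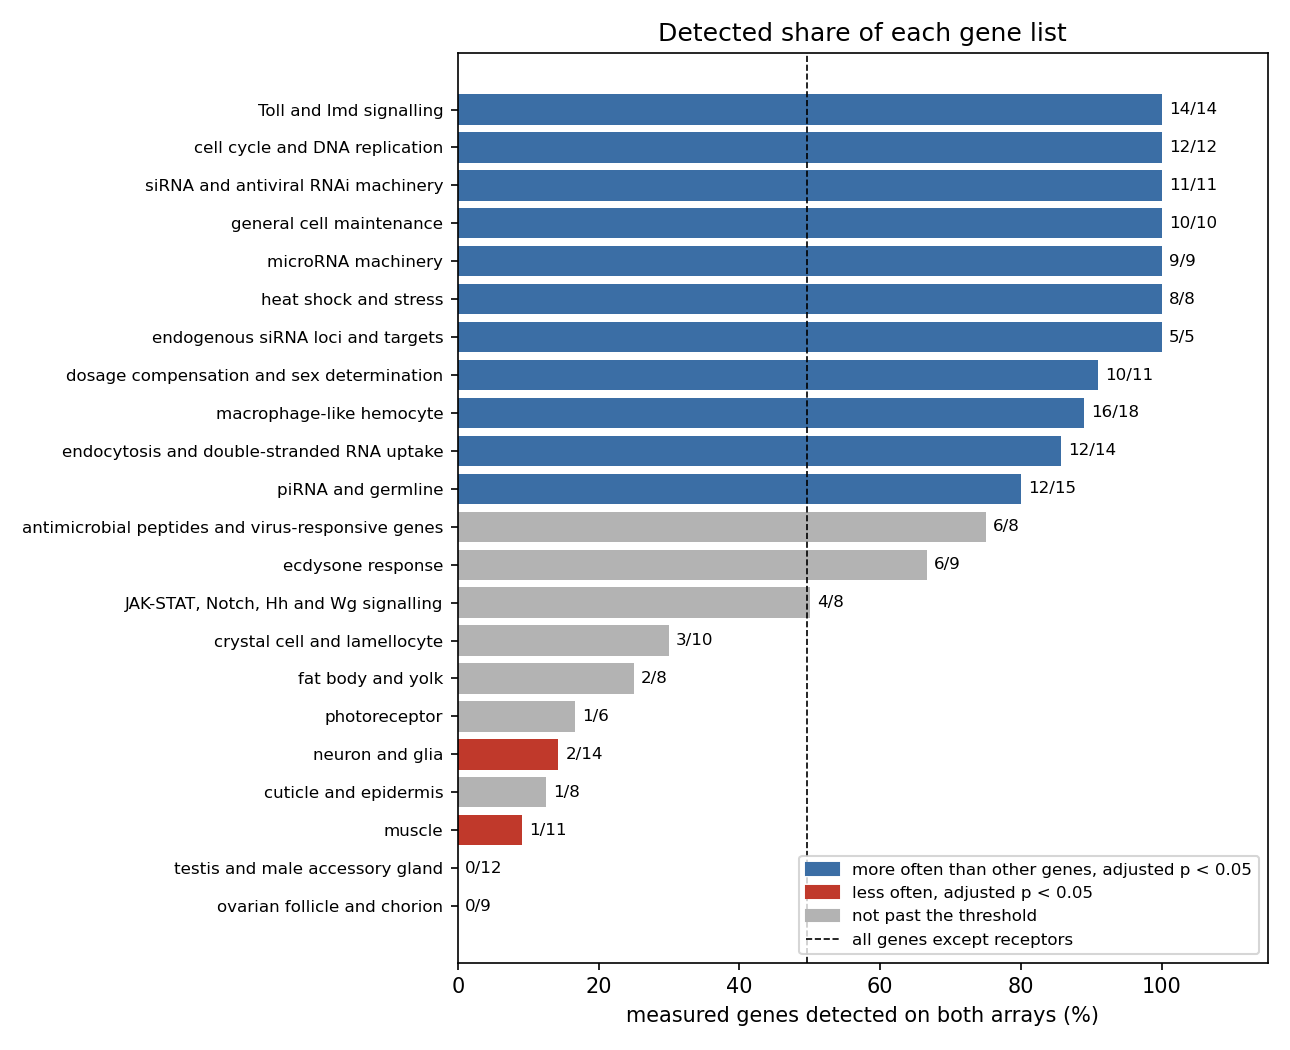
Percent of the measured genes of each list that were detected on both arrays, with detected and measured numbers at the bar ends and the share of all non-receptor genes (49.5%) as a dashed line; blue lists were detected more often and red lists less often than other genes (adjusted p under 0.05, Fisher's exact test), grey lists did not pass. All 14 Toll and Imd genes and all 11 siRNA genes were detected, and 0 of the 12 testis and accessory gland genes.

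All 14 Toll and Imd immune signalling genes were detected (Fisher's exact test, adjusted p = 0.00117), with Tl, the Toll receptor gene, at 2980 ± 300, its ligand gene spz at 4068 ± 278, and the adaptor and kinase genes tub and pll at 1590 ± 54.6 and 1208 ± 70.9. With the 99th percentile limit the share of Toll and Imd genes was 78.6%, and the call was kept. Of 8 antimicrobial peptide and virus-responsive genes 6 were detected (adjusted p = 0.227, Fisher's exact test). These included DptB at 1997 ± 653, AttD at 1297 ± 219, CecB at 378 ± 69.1 and Drs at 1573 ± 95.2. Def (59.3 ± 14.5) and the virus-induced gene Vago (4.71 ± 0.394) were below the limit. All 12 cell cycle genes were detected (adjusted p = 0.00239, Fisher's exact test), among them the cyclin genes CycB (3115 ± 66.3), CycB3 (1005 ± 10.8), CycE (2033 ± 85.3) and CycD (645 ± 92.6). All 10 general maintenance genes were detected (adjusted p = 0.00325, Fisher's exact test), with RpL32 at 18950 ± 2706 and Gapdh1 at 5378 ± 793.

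Of 14 genes for endocytosis and dsRNA uptake 12 were detected (Fisher's exact test, adjusted p = 0.0138). The scavenger receptor gene Sr-CI was at 2067 ± 386, and the clathrin genes Chc and Clc at 6672 ± 62.7 and 4907 ± 126. Its relative Sr-CII (2.67 ± 0.486) and ninaD (8.2 ± 3.69), also a scavenger receptor gene, were not detected. The call was lost with the limit from 50 control probe sets (85.7%) and among genes with a single probe set (81.8%). Of 11 dosage compensation and sex determination genes 10 were detected (adjusted p = 0.013, Fisher's exact test). Here msl-2, the male-specific subunit of the dosage compensation complex, was at 1271 ± 58.8, msl-1 at 508 ± 58.2, msl-3 at 758 ± 106 and mle at 1061 ± 56.8, while dsx was not detected at 57.1 ± 5.23. That call was lost when all probe sets of a gene had to pass (72.7%) and with the limit from 50 control probe sets (90.9%). All 8 heat shock and stress genes were detected (adjusted p = 0.00955, Fisher's exact test), including Hsp68 (843 ± 303), Hsp26 (2941 ± 1478), Hsp27 (1738 ± 414) and Hsf (1667 ± 143). With the limit from 50 control probe sets that call was lost (100%).

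Detection in 2 other lists was mixed and did not pass the test. In the list of JAK-STAT, Notch, Hedgehog and Wingless genes, of which no Wingless gene and, for Notch, only Delta were measured, 4 of 8 were detected (Fisher's exact test, adjusted p = 1). Stat92E (4385 ± 247) and its receptor gene dome (755 ± 114) passed the limit. The ligand genes upd1 (5.05 ± 1.91), Delta (48.3 ± 16.7) and hh (7.06 ± 7.19) and the transcription factor gene ci (67.4 ± 9.93) did not. Outside the naming rule, the Hedgehog genes smo (790 ± 157) and ptc (163 ± 20.2) also passed. On replicate 1 ptc lay close to the limit, at 149 against 146. In the ecdysone list 6 of 9 were detected (adjusted p = 0.36, Fisher's exact test). The receptor genes EcR (874 ± 32.9) and usp (933 ± 0.533) and the response genes br (2384 ± 34.2) and ftz-f1 (1483 ± 3.44) passed, and the nuclear receptor genes Hr4 (87.2 ± 5.21) and Hr3 did not.

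Overlapping genes are one place where both strands can be transcribed, and joint detection of neighbours was compared. No strand was used, so pairs on the same strand are included. In 764 of 1429 overlapping neighbouring pairs (53.5%) both genes were detected, in 460 only one, and in 205 neither. Random re-pairing of the members gave 676 to 707 such pairs in 95% of draws, with 691 expected (permutation test, p = 2e-05, the smallest the draws can give). Among 6275 separate neighbours both genes were detected in 2427 (38.7%), where re-pairing gave 1795 to 1873 (permutation test, p = 2e-05, again the smallest possible). The share with both detected was 14.8 percentage points higher in overlapping than in separate pairs (Fisher's exact test, p = 3.05e-24). Single genes were also detected more often in overlapping pairs, 69.4% against 54.6%, and re-pairing alone gave expected shares of 48.4% and 29.2%, a difference of 19.2 points. Observed over expected was 1.10 in overlapping and 1.32 in separate pairs. By gap the share was 49.2% up to 200 bp, 51.1% at 201 to 500 bp, 29.1% at 501 to 1000 bp and 8.36% at 5001 to 50000 bp. By overlap it was 54.9% at 1 to 99 bp and 56.0% at 100 to 499 bp. In the 210 pairs overlapping by 500 bp or more it was 42.9%, below separate pairs with a gap of up to 500 bp. Against separate pairs with a gap of up to 1000 bp the excess was 7.82 points, and against those of up to 200 bp it was 4.26 points (Fisher's exact test, p = 0.0148). Against those with a gap of 201 to 500 bp it was 2.37 points and did not pass (Fisher's exact test, p = 0.184). A gene can belong to more than one pair, so pairs are not fully independent.

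**Figure D2:**
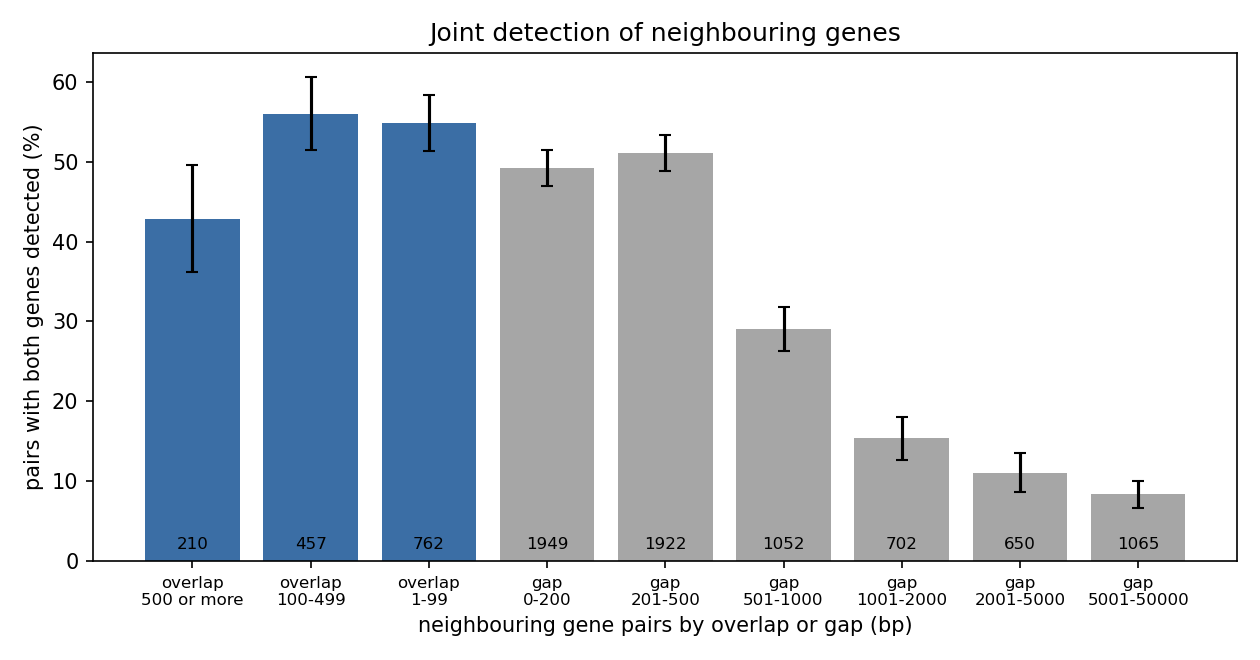
Percent of neighbouring protein-coding gene pairs with both genes detected, by length of the overlap (blue) or gap (grey) in bp, with 95% normal-approximation intervals and the number of pairs inside each bar. The share was 42.9% at overlaps of 500 bp or more, 54.9% at overlaps of 1 to 99 bp, 51.1% at gaps of 201 to 500 bp and 11.1% at gaps of 2001 to 5000 bp.

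The last comparison was between the duplicates, 1 array each, which gives no test. The SD of the log2 difference over detected probe sets was 0.23 (95% bootstrap interval 0.22 to 0.23), and 0.317% of them differed by over 2-fold. Across these probe sets, which are not independent replicates, Pearson's r of the log2 signals was 0.989. The spread was 1.12 below the limit. Over 4 equal classes of rising signal among detected probe sets it was 0.27, 0.22, 0.21 and 0.20. Of the 23 detected probe sets that differed by over 2-fold, 20 were higher on replicate 2 and 3 on replicate 1, and 14 of the 23 had no single gene name. With median scaling the split was 18 and 5. Over all probe sets, detected or not, 1811 were over 2-fold higher on replicate 2 and 1616 on replicate 1.

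The named gene with the largest difference was MtnA, a metallothionein gene that responds to metals, at 2926 on replicate 1 and 10874 on replicate 2, or 3.72-fold. All 10 named genes with the largest differences were higher on replicate 2. MFS3, a transporter gene, differed by 1.29 on the log2 scale, the sugar transporter gene Tret1-1 by 1.09, JhI-26 by 1.09 and the small heat shock gene Hsp26 by 1.07. CG8620 (1.16), CG8915 (1.08), c(2)M (1.08), the cytochrome P450 gene Cyp6a23 (1.02) and the glutathione transferase gene GstD9 (1.00) made up the rest. All 8 heat shock and stress genes were higher on replicate 2, with a median of 0.18, at percentile 99.4 among random lists of like signal. With median scaling 7 of them were higher. All 10 general maintenance genes were also higher on replicate 2, with a median of 0.28 (percentile 98.1) that was 0.06 after quantile normalization and 0.22 after median scaling. The 6 detected antimicrobial peptide and virus-responsive genes were all lower on replicate 2, with a median of -0.36 (percentile 0.01), also after quantile normalization or median scaling. Of 16 detected hemocyte markers 4 were higher there, with a median of -0.09 (percentile 0.58). The siRNA loci did not move as a group: 3 of 5 were higher, with a median of 0.20 (percentile 98.1) below their SD of 0.24. The 4 detected JAK-STAT and Hedgehog genes had a median of -0.21 (1 of 4 higher, percentile 2.33). In lists this small the median rests on 1 or 2 genes, and the percentiles were not adjusted for the number of lists. The median difference over all detected probe sets was -0.00231, while the 18 hybridisation control probe sets were all higher on replicate 2, by 0.30 at the median.

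**Figure D3:**
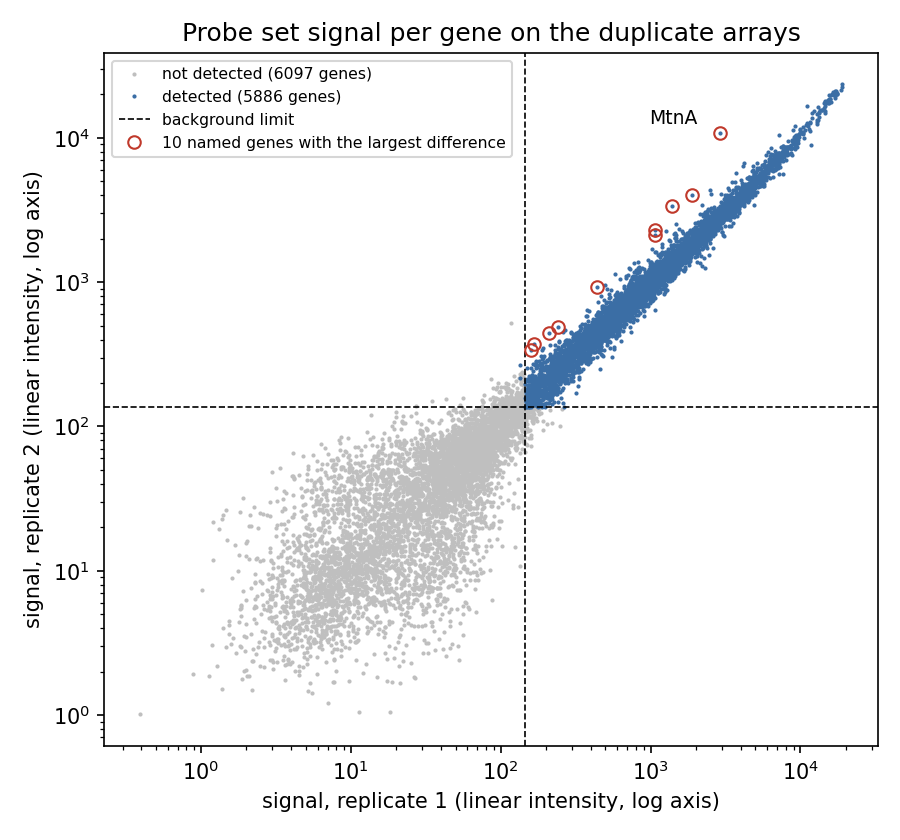
Signal of each gene's brightest probe set on replicate 1 (x axis) and replicate 2 (y axis), linear intensities on log axes, with the background limits dashed. The 5886 detected genes lie close to the diagonal, and the 10 named genes with the largest difference (red circles) lie above it.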

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

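All tests of explanations in this part were chosen after the results were seen. Signals outside the comparisons of named genes were found in 3 places. Of 4720 probe sets with no gene in the annotation, other than controls, 728 (15.4%) were above the limit on both arrays. Of 402 probe sets assigned to several genes, 205 were above it. Among control probe sets whose names did not place them with the hybridisation or fly maintenance controls, 2 were above it as well, at signals of 12991 ± 1823 and 167 ± 10.6. What these 2 probe sets detect was not named in the tables used here. Their names hold sequence identifiers that were not looked up. A spiked control or another added sequence therefore stays possible for either, and neither is evidence of a fly transcript.

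A first pattern for follow-up is the one-sided difference between the duplicates, in which 20 of 23 probe sets that differed by over 2-fold were higher in replicate 2, those of MtnA and Hsp26 among them. A difference in signal distribution that quantile normalization removes is argued against, since 20 of 23 over 2-fold were still higher in replicate 2 after it. A difference in overall scale stays open in part. With median scaling the split was 18 and 5. The 18 spiked hybridisation controls were all higher in replicate 2, by 0.30 at the median and at most 0.52 (log2). Hsp26, at 1.07, exceeded 2-fold by less than that median, and MtnA, at 1.89, by more. Noise of dim probe sets is argued against only for those of the 23 that were bright. Over 4 equal signal classes of detected probe sets, 9 lay in the brightest and 5 in the dimmest. The limit had to be passed on both arrays, which keeps the dimmest pairs out of this count, so the 5 alone cannot decide. The labels give no batch or day for the duplicates, so a technical batch stays open, and no biological explanation was tested.

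A second pattern is the gustatory receptor gene Gr61a, whose signal was 1490 ± 46.2 and lay at 10.4 and 10.7 times the limit on the 2 arrays. Gr61a was singled out after its value was seen; the other 4 receptor genes above the limit were Gr5a, Gr94a, Or65c and Or74a. A defect of a single array is argued against, because the arrays differed by 1.04-fold at this probe set. Signal from another gene over the same span stays open: 0 detected genes are annotated over Gr61a in the gene table used here, but that table may be incomplete and the probe sequences were not used. Expression of the receptor in S2 cells is the other open explanation and was not tested.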

How the results depend on the processing

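No paired analysis was possible because there is a single group. The planned tests by strand and all their alternatives were not run, for want of strands. The limit from 50 control probe sets, the limit without Gr61a, the gaps of up to 200 bp and of 201 to 500 bp and all tests of neighbours were chosen after seeing the data. Detected genes ranged from 5251 (99th percentile limit) to 6972 (limit from the 50 control probe sets), against 5886. The excess of overlapping over all separate neighbours kept its direction under every alternative run and passed Fisher's exact test, from 4.26 points (gap up to 200 bp) to 19.2 (gap up to 50000 bp), except against gaps of 201 to 500 bp (2.37 points). Of the 22 lists, 15 passed the test, and 12 to 17 did under the other alternatives (13 to 14 with single arrays, and 13 of 19 with the limit from the photoreceptor, testis and chorion lists, which were then not tested), except that 7 passed with the limit from the 50 control probe sets, where 58.5% of other genes were detected. No called list reversed its direction. With that limit the calls were lost for the piRNA list (86.7%), siRNA loci (100%), neuron and glia (28.6%), ovarian follicle (22.2%), testis (25.0%), dosage compensation (90.9%), heat shock (100%) and endocytosis (85.7%). The siRNA loci call was also lost with the 90th percentile limit, detection on at least 1 array, each array alone and genes with a single probe set (100% in each), and with all probe sets required (80.0%). Requiring all probe sets also ended the piRNA (73.3%) and dosage compensation (72.7%) calls, as leaving out replicate 2 did for piRNA (80.0% to 86.7% over the single arrays). Restriction to genes with a single probe set ended those for neuron and glia (20%) and endocytosis (81.8%). Where a call was lost at 100%, no measured member had become undetected. With the limit from the 50 control probe sets, 58.5% of other genes were detected, against 49.5% with the main limit. For the other changes the cause was not tested. Calls gained were cuticle and epidermis (12.5%) with the 90th percentile limit or detection on at least 1 array, and fat body (0%) and photoreceptor (0%) with the 99th percentile. The SD of the log2 difference was 0.22 with a pseudocount of 16 and 0.89 over all probe sets, of which 3427 differed by over 2-fold against 23 of the detected ones. Signal over background therefore limits what the arrays can compare, with an SD of 1.12 below the limit. Of 122 named genes, the 99th percentile limit ended detection of 7, and the limit from the 50 control probe sets added 6, piwi, NimC1, Cp15, Hr4, brp and chp.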

Other observations

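The families below and all their tests were chosen after the data were seen. Gene families defined by their symbols gave a wider view of what these cells expressed, as shares of measured genes detected against about 49% to 50% of other genes (two-sided Fisher's exact test, adjusted over 22 families). All 69 mitochondrial ribosomal protein genes were detected (Fisher's exact test, adjusted p = 1.61e-20), 28 of 29 aminoacyl-tRNA synthetase genes (1.96e-07), 19 of 20 nucleoporin genes (3.93e-05), 35 of 41 cytosolic ribosomal protein genes (6.31e-06), and 26 of 32 genes of respiratory complex I (0.000449). Not all such families stood so high. A family defined by symbols may take in relatives of the named subunits, so its share is not the expressed share of a complex. Of 41 proteasome subunit genes 28 were detected (Fisher's exact test, adjusted p = 0.0253). Of 31 vacuolar ATPase subunit genes 16 were, which did not pass (Fisher's exact test, adjusted p = 0.859). At the other end were 0 of 24 Osiris genes (Fisher's exact test, adjusted p = 4.37e-07), 0 of 13 Jonah serine protease genes (0.000413), 2 of 66 cuticular protein genes of the Cpr family (6.55e-16), 2 of 53 ionotropic receptor genes (2.33e-12), 2 of 47 odorant-binding protein genes (8.81e-11) and 1 of 27 pickpocket channel genes (1.31e-06). Families of detoxifying enzymes differed in their counts. Of 83 cytochrome P450 genes 21 were detected (Fisher's exact test, adjusted p = 1.83e-05) and of 35 UDP-glycosyltransferase genes 6 (0.000214), while 20 of 34 glutathione S-transferase genes were detected, a share that did not pass the test (0.354). The metallothionein genes MtnB, MtnC and MtnD were below the limit, and MtnA was above it.

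Between the duplicates, several of these families moved together. Of 28 detected aminoacyl-tRNA synthetase genes 23 were higher on replicate 2, with a median log2 difference of 0.22, above all 10000 random lists of like signal. For translation initiation factors the median was 0.13 (26 of 32 higher, percentile 99.98) and for glutathione S-transferases 0.14 (14 of 20 higher, percentile 99.99). Of 35 cytosolic ribosomal protein genes 33 were higher on replicate 2, with a median of 0.23 that lay at percentile 61.3 among lists of like signal and was 0.01 after quantile normalization and 0.17 after median scaling. These genes could be drawn into their own random lists, so a middling percentile does not show that other genes of like signal moved as they did. Complex I genes went the other way, with a median of -0.12 and 4 of 26 higher on replicate 2 (percentile 0.2). For synthetases, initiation factors, transferases and complex I the medians after quantile normalization were 0.22, 0.08, 0.16 and -0.12, and after median scaling 0.16, 0.07, 0.08 and -0.18. These are differences between 2 single arrays and have no replicate check.

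All tests of the last pattern, the joint detection of overlapping neighbours at 14.8 percentage points above separate neighbours, were chosen after it was seen. More frequent detection of the single members, whatever their partner, is a candidate explanation that goes with the values, since re-pairing alone gave a difference of 19.2 points, larger than the one seen. A tighter coupling of the members in overlapping pairs than in separate neighbours of all gaps is argued against: pooled within classes of overlap or gap, the odds ratio of joint detection was 0.715 times that of separate pairs (95% interval 0.549 to 0.932, with no allowance for genes shared between pairs), and without classes it was 2.96 against 4.99. Against pairs with a gap of up to 200 bp alone coupling stays open, because 2.96 (95% interval 2.33 to 3.76) and 3.89 (3.19 to 4.75) overlap. Closeness of the genes alone stays open too. Overlapping pairs of all lengths exceeded pairs with a gap of up to 200 bp by 4.26 points (0.851 to 7.67). Over those with a gap of 201 to 500 bp the excess was 2.37 points, which did not pass Fisher's exact test. Re-pairing alone gave 6.29 and 6.53 points, so more frequent detection of single members goes with these values too. The longest overlaps, of 500 bp or more, went the other way, with 42.9% against 49.2% and 51.1% in these 2 gap classes. Their single members were detected in 61.9%, against 64.9% and 64.7%.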
